A study of Mus musculus with 12 samples.

How the data were processed

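RNA-seq counts were used for 8 libraries of mouse embryonic fibroblasts (MEFs), in 4 groups of 2: wild-type and Carm1 knockout cells, each in rich medium and after 18 h in glucose-free medium. Per the labels, both genotypes were C57BL/6 cells at passages 3 to 5, the growth medium held 10% fetal bovine serum, and the starvation medium held 10% dialyzed serum, so the media differed in dialysis as well as in glucose. A further 4 chromatin immunoprecipitation libraries of the series are not analysed here. Groups and replicate numbers were taken from the sample titles, and each column of the deposited table was matched to a sample by its name.

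The deposited values are whole-number counts of reads per RefSeq transcript of the mouse mm9 build. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.9, and bedtools was used. Strand, the handling of reads with several matches and the counted part of each transcript are not given in the sources used here. The count table held 31055 transcripts of 23366 gene symbols, and 4447 symbols had several transcripts. Among the 3118 such symbols with at least 100 counts, the transcript with the lowest total held at least 90% of the highest total in 72.9%, so transcripts of a gene repeat the same reads. Each gene was therefore represented by its transcript with the highest total. Antisense, overlapping and near-identical genes, ribosomal protein and histone genes among them, could share reads in such a table, and their values are less certain.

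Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3, which kept 13882 genes, and library sizes were scaled by trimmed mean of M values (TMM). All 8 libraries entered a fit with a mean per group, so that the groups share an estimate of the spread (biological coefficient of variation 18.5%). Quasi-likelihood tests gave 5 contrasts: starvation in wild-type cells, starvation in knockout cells, knockout against wild type in rich medium, the same after starvation, and the difference between the starvation responses of the genotypes. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are CPM on TMM-scaled library sizes, computed here. Total counts over genes ran from 8447016 to 28155438 per library, at which 3 counts correspond to 0.355 and 0.107 CPM. A fold against a group with 0 counts is a lower bound computed against 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact 95% interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

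The members of 42 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and most of the other settings listed last. For 38 lists with at least 5 tested members, camera of limma 3.58.1 compared log2 CPM (prior count 2) of the members with all other genes at a preset correlation of 0.01, with adjustment over the lists of a contrast. An estimated correlation and fry were run beside it. Counts of list members passing the threshold are adjusted over all genes tested, and a second count, adjusted over the list alone, is given where it differs. The text names genes from among Carm1, sex-linked genes, the 8 genes with the largest rise and the 8 with the largest fall per contrast (at least 5 CPM in a group, replicates of the groups apart, no predicted genes), and the 4 members with the smallest p per list and contrast. A gene named for a contrast is also given its value in others. Ulk1 and Map1lc3b fall outside this rule and were chosen after their values were seen. Some genes the rule covers are not reported here.

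The fit was tested on simulated counts for 13882 genes, 200 of them changed. Of the genes changed 4-fold, it recovered 69.7% for wild-type starvation, 77.3% for knockout starvation, 83.3% for knockout against wild type in rich medium, 78.8% for the same after starvation and 54.5% for the difference between responses. At 2-fold the shares were 7.46%, 14.9%, 17.9%, 4.48% and 1.49%, in the same order. False calls were 1 of 52, 6 of 68, 2 of 69, 4 of 59 and 1 of 38 calls. All simulated libraries had the same spread for a gene, unlike the data. These rates were therefore not obtained for a group with a wider spread, such as the knockout rich pair, or for changes in more genes. In a simulated rise of the lysosome list by 0.5 on the log2 scale, camera called that list (adjusted p = 3.8e-22) and 0 others. Genes were simulated independently, so this cannot show how often lists of correlated genes are called falsely at the preset correlation.

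The analysis was repeated with relative log expression (RLE) factors, total counts, no filter, a stricter filter (5 CPM in at least 2 libraries), DESeq2 1.42.0, limma-voom, a replicate block, a fit of only the 4 libraries compared, a minimum change of 1.5-fold, another prior count, and each library left out in turn. Library quality weights, counts summed over transcripts and the transcript with the lowest total were added after seeing the data, as were list counts without replicate 1 of the knockout in rich medium, which differed widely from replicate 2. Gene positions came from a RefSeq gene table of the GRCm38.p6 assembly, which differs from the build of the counts. It was used only for names, gene spans and which genes share a chromosome, and 99.5% of the tested genes matched it. Figures were drawn with matplotlib 3.10.9.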

Results

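RNA was sequenced from mouse embryonic fibroblasts, primary connective tissue cells grown from embryos, that were wild type or carried a knockout of Carm1. This gene encodes CARM1, which methylates arginine residues of histone H3 and other proteins and acts as a transcriptional coactivator. Cells of each genotype were sampled in rich medium or after 18 h in glucose-free medium, with 2 libraries per group. The study asked how CARM1 contributes to the expression of autophagy genes in starved cells. No title gives a rich-medium library at 18 h, so time in culture and the change of medium may also contribute to the starvation contrasts. Gene counts totalled 20495124 and 26907501 in the wild-type rich libraries and 24324112 and 28155438 in the wild-type starved libraries. They totalled 8447016 and 21529669 in the knockout rich libraries, and 26641106 and 24312467 in the knockout starved libraries. Levels are given as mean CPM ± SD (n = 2) and changes as log2 fold changes ± SE, with Benjamini-Hochberg adjusted p-values from the edgeR quasi-likelihood test or from camera for gene lists. The labels do not say that replicates were separate cultures. The p-values measure only the spread between these samples, which may be technical.

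Carm1 transcripts were lower in each knockout library than in any wild-type library. Carm1 stood at 206 ± 2.10 CPM in wild-type rich cells and 169.9 ± 8.01 CPM in wild-type starved cells. In the knockout it stood at 59.4 ± 16.0 CPM in rich medium and 56.3 ± 3.35 CPM after starvation, 28.9% and 33.1% of the wild-type means (log2 fold changes -1.78 ± 0.19 and -1.59 ± 0.19, adjusted p = 0.000377 and 0.000421). Which exons the knockout removes is not given in the sources used here. The genotypes also differed at Xist, the RNA that coats the inactive X chromosome of female cells, which had 18657 to 23751 counts in the wild-type libraries and 0 to 6 in the knockout libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 8 libraries. As no library had counts for them, the data do not show whether these genes could be detected, and their absence is not established.

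**Figure D1:**
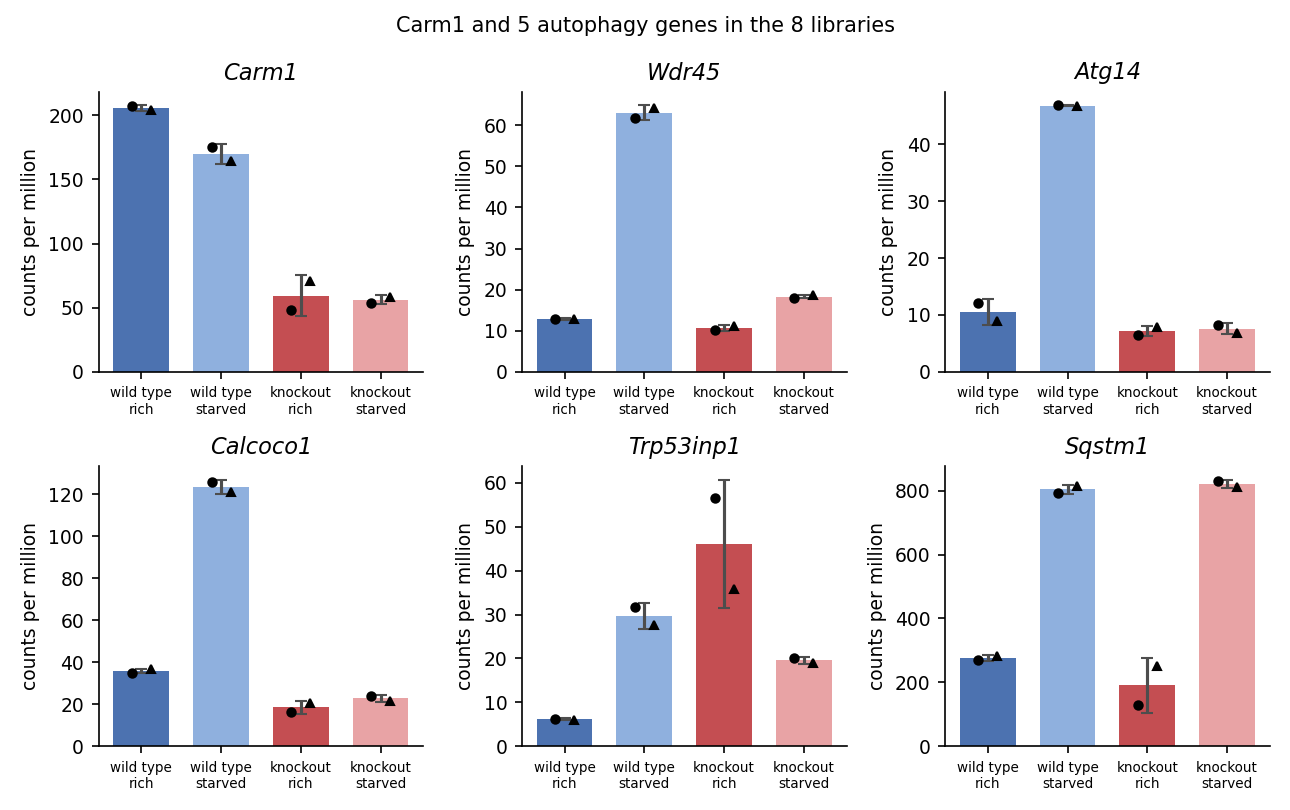
CPM of Carm1 and 5 autophagy genes in the 4 groups, where bars are means, error bars are SD (n = 2), circles are replicate 1 and triangles are replicate 2. Wdr45, Atg14 and Calcoco1 were several times higher in starved than in rich wild-type cells, Trp53inp1 changed in opposite directions in the 2 genotypes, and Sqstm1 rose in both.

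Replicates lay close together in 3 groups and far apart in the knockout rich group. The standard deviation across genes of the log2 ratio between replicates was 0.125 in wild-type rich, 0.136 in wild-type starved and 0.122 in knockout starved libraries, against 0.748 in knockout rich libraries. In that group 1633 of 9088 genes with at least 10 CPM differed by more than 2-fold between the replicates, against 1 or 2 genes in each other group. Replicate 1 of the knockout rich group, the library with the fewest counts, was also the farther of the pair from the knockout starved libraries (0.908 and 0.937, against 0.627 and 0.624 for replicate 2). Since the groups share an estimate of the spread, this pair enters each comparison. The shared estimate as a rule lies below the spread of this pair and above that of the other groups. The SEs and p-values are therefore likely too small where the knockout rich group is compared and too large in the other contrasts. Counts of genes without replicate 1 are given for each comparison, with counts for some of the lists. In a fit without either knockout rich replicate, the lone library left adds nothing to the spread, which then comes from the closer pairs. Calls gained in such a fit are therefore likely too many and do not by themselves show a change.

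**Figure D2:**
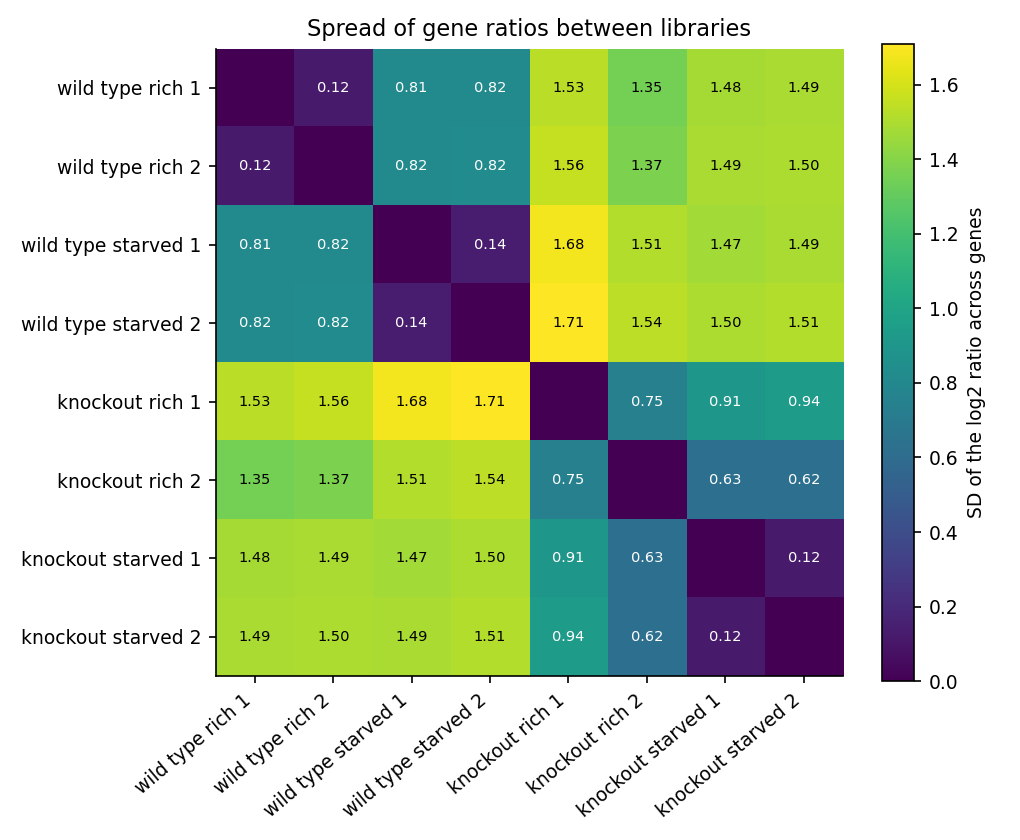
Standard deviation across genes of the log2 ratio of CPM between each pair of the 8 libraries, as colour and number. Replicates of 3 groups lie at 0.122 to 0.136 and the knockout rich replicates at 0.748, while wild-type and knockout libraries lie at 1.35 or more from each other.

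Starvation of wild-type cells raised genes of the integrated stress response, endoplasmic reticulum (ER) chaperones, autophagy genes and ribosomal protein genes. Genes of interferon and inflammatory signalling, mitosis, and sterol and fatty acid synthesis fell. In all 4561 of 13882 genes changed, 2060 higher and 2501 lower. Leaving out replicate 1 or replicate 2 of the knockout rich group raised the count to 9498 or 9511, a fit of the 4 wild-type libraries alone gave 9382, and leaving out any wild-type library lowered it to between 1626 and 1818.

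Of 51 tested members of the autophagy list, 19 rose and 3 fell (23 and 3 adjusted over the list alone), with a median log2 fold change of 0.45 (adjusted p = 5.68e-06; adjusted p = 0.199 with an estimated correlation). The largest rises among the genes named here were in Wdr45, which binds phosphoinositides on forming autophagosomes (2.29 ± 0.14, 12.8 ± 0.149 to 63.0 ± 1.84 CPM), in Trp53inp1, a p53-inducible regulator of autophagy (2.27 ± 0.24), and in Atg14, a subunit of the phosphatidylinositol 3-kinase that starts autophagosome formation (2.16 ± 0.21, 10.5 ± 2.30 to 46.8 ± 0.0334 CPM). The receptor Calcoco1 rose by 1.79 ± 0.15, the ubiquitin-like conjugation protein Atg12 by 1.61 ± 0.12, the kinase Pik3c3 by 1.04 ± 0.13, the cargo receptors Nbr1 and Sqstm1 by 1.34 ± 0.14 and 1.54 ± 0.28, and the Atg8 family member Gabarapl1 by 1.20 ± 0.13. Smaller rises were found for Map1lc3b (0.78 ± 0.14) and the initiating kinase Ulk1 (0.81 ± 0.23, adjusted p = 0.0332), both chosen after their values were seen. The call of Ulk1 was lost without any of 6 libraries in turn, that of Map1lc3b without either wild-type rich library or wild-type starved replicate 2, and that of Sqstm1 without either wild-type rich library. Of 63 lysosome genes, 22 rose and 5 fell (23 and 5 adjusted over the list alone), with a median of 0.40 (adjusted p = 0.00114; adjusted p = 0.38 with an estimated correlation). Among them the iduronidase Idua rose by 1.70 ± 0.19, the proton pump subunit Atp6v1c1 by 1.15 ± 0.14 and the acid phosphatase Acp2 by 0.97 ± 0.12, while the fucosidase Fuca1 changed by -1.28 ± 0.17. Without replicate 1 of the knockout rich group, 38 autophagy genes and 42 lysosome genes rose, and 4 and 15 fell. Without any wild-type library in turn, 9 to 12 autophagy genes and 11 to 14 lysosome genes rose.

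Genes of the stress responses rose almost throughout. Of 33 genes of the ATF4 and integrated stress response list, 27 rose and 0 fell (adjusted p = 8.09e-13; adjusted p = 0.199 with an estimated correlation). Ddit3, a transcription factor induced by unresolved stress, went from 19.5 ± 0.190 to 509 ± 47.2 CPM (4.71 ± 0.17, adjusted p = 4.55e-05). The transsulfuration enzyme Cth rose by 3.04 ± 0.21, the cationic amino acid transporter Slc7a3 by 3.67 ± 0.27 and the mitochondrial folate enzyme Aldh1l2 by 2.24 ± 0.14. Of 25 ER chaperone and unfolded protein response genes, 23 rose and 0 fell (adjusted p = 8.09e-13; adjusted p = 0.0207 with an estimated correlation, and 0.131 with it when replicate 1 of the knockout rich group was left out). Among them were Herpud1 (3.55 ± 0.18) and Sel1l (2.02 ± 0.12), which act in the degradation of misfolded ER proteins, and the secreted ER stress protein Manf (2.59 ± 0.13). Of 20 cytosolic tRNA synthetases, 11 rose and 2 fell (adjusted p = 0.00078; adjusted p = 0.133 with an estimated correlation). Ribosomal protein genes rose in 38 of 77 cases and fell in 0 (43 and 0 adjusted over the list alone; adjusted p = 1.25e-10; adjusted p = 0.353 with an estimated correlation). Rps12 rose by 0.90 ± 0.13 and Rps20 by 0.95 ± 0.14. All 77 rose without replicate 1 of the knockout rich group.

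Interferon-stimulated genes fell in 26 of 32 cases and rose in 0 (29 and 0 adjusted over the list alone; adjusted p = 1.93e-12; adjusted p = 0.0207 with an estimated correlation, and 0.131 with it when replicate 1 of the knockout rich group was left out). They included Rtp4 (-3.43 ± 0.19), Ifit3 (-4.13 ± 0.33) and the chemokine gene Cxcl10 (-2.53 ± 0.19). Of 19 NF-kB and inflammatory genes, 11 fell and 1 rose (11 and 2 adjusted over the list alone; adjusted p = 7.35e-05; adjusted p = 0.133 with an estimated correlation). The chemokine gene Ccl2 went from 62.0 ± 0.683 to 1.73 ± 0.195 CPM (-5.16 ± 0.15), and Cxcl1, the growth factor gene Csf1 and the NF-kB inhibitor Tnfaip3 changed by -5.41 ± 0.15, -2.90 ± 0.12 and -3.91 ± 0.17. Immediate early genes fell in 10 of 20 cases and rose in 1 (adjusted p = 0.00276; adjusted p = 0.304 with an estimated correlation), with the transcription factor Egr1 at -3.15 ± 0.13. Contractile genes and targets of the coactivator YAP fell in 11 of 18 cases and rose in 3 (adjusted p = 0.00469; adjusted p = 0.304 with an estimated correlation). The matricellular protein genes Ctgf and Cyr61 changed by -2.89 ± 0.12 and -2.28 ± 0.16.

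Of 32 mitosis genes, 26 fell and 0 rose (adjusted p = 1.24e-10; adjusted p = 0.165 with an estimated correlation). The mitotic kinases Plk1 and Aurka changed by -2.56 ± 0.15 and -1.90 ± 0.14 and the ubiquitin-conjugating enzyme Ube2c by -1.97 ± 0.12. DNA replication genes went both ways, 11 higher and 5 lower of 38 (15 and 6 adjusted over the list alone; adjusted p = 0.0269; adjusted p = 0.303 with an estimated correlation). The origin licensing factor Cdc6 rose by 0.96 ± 0.13, while the ribonucleotide reductase subunit Rrm2 changed by -1.14 ± 0.11. Cholesterol synthesis genes fell in 16 of 24 cases and fatty acid synthesis genes in 6 of 14, with 0 rises in either (17 and 6 falls adjusted over the list alone; adjusted p = 3.95e-05 and 0.000756; adjusted p = 0.133 for both with an estimated correlation). The fatty acid elongase Elovl6 and the desaturase Scd2 changed by -3.81 ± 0.15 and -3.46 ± 0.16. Glycolysis genes fell in 11 of 22 cases and rose in 0 (12 and 0 adjusted over the list alone; adjusted p = 0.00155; adjusted p = 0.579 with an estimated correlation). Without replicate 1 of the knockout rich group, 23 DNA replication genes rose and 7 fell, and 13 fatty acid synthesis and 18 glycolysis genes fell. Among the genes with the largest changes, the sterol acyltransferase Soat2 rose by 6.29 ± 0.34 and the transcription factor Klf15 by 4.36 ± 0.39, and the growth factor Igf1 changed by -6.03 ± 0.50. Car6, a secreted carbonic anhydrase, was at least 81.6-fold higher and the chemokine gene Cxcl5 at least 104-fold lower in starved cells, each against a group with 0 counts.

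**Figure D3:**
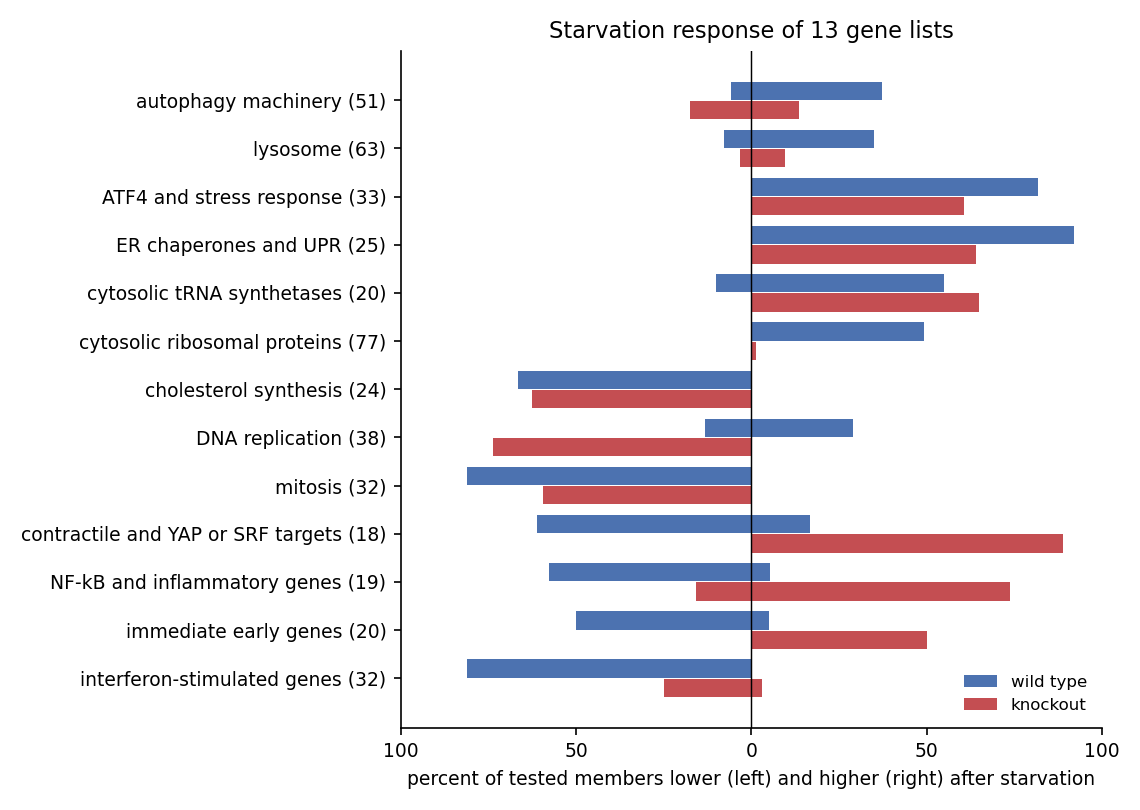
Percent of tested members (number in parentheses) of 13 gene lists that passed the threshold as lower (left) or higher (right) after starvation, in wild-type and knockout cells. The ATF4 list rose in both genotypes, with 27 and 20 of 33 members, whereas the contractile list had 11 of 18 members lower in wild-type and 16 of 18 higher in knockout cells.

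Starvation of knockout cells also raised stress response and ER chaperone genes and lowered genes of cholesterol synthesis and mitosis. Contractile, inflammatory and immediate early genes rose, and DNA replication genes fell. In all 2528 genes changed, 1171 higher and 1357 lower. The count was 7096 without replicate 1 and 8419 without replicate 2 of the knockout rich group, 280 and 278 without the first and second knockout starved library, and between 1260 and 1354 without any wild-type library. A fit of the 4 knockout libraries alone with edgeR called 0 genes, with a smallest adjusted p of 0.0501 and 2831 genes at an unadjusted p under 0.05, and limma-voom with library quality weights over all 8 libraries called 1319.

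Of the ATF4 and integrated stress response list, 20 of 33 members rose and 0 fell (25 and 0 adjusted over the list alone; adjusted p = 3.6e-09; adjusted p = 0.272 with an estimated correlation). Ddit3 rose by 3.20 ± 0.16 and Cth by 2.26 ± 0.20. The phosphatase subunit Ppp1r15a, which reverses the translational block of the stress response, rose by 3.84 ± 0.32. ER chaperone genes rose in 16 of 25 cases and fell in 0 (17 and 0 adjusted over the list alone; adjusted p = 1.75e-07; adjusted p = 0.0452 with an estimated correlation). The major ER chaperone Hspa5 rose by 2.61 ± 0.14, Herpud1 by 2.34 ± 0.17 and the transcription factor Xbp1 by 1.69 ± 0.15. Cytosolic tRNA synthetases rose in 13 of 20 cases and fell in 0 (16 and 0 adjusted over the list alone; adjusted p = 1.39e-07; adjusted p = 0.0452 with an estimated correlation). Without replicate 1 of the knockout rich group, 27, 21 and 18 members of these lists rose and 3, 0 and 0 fell. None of them then passed with an estimated correlation (adjusted p = 0.142, 0.122 and 0.102).

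Contractile genes and YAP targets rose in 16 of 18 cases and fell in 0 (17 and 0 adjusted over the list alone; adjusted p = 1.21e-11; adjusted p = 0.105 with an estimated correlation). Cyr61 went from 41.7 ± 7.86 to 896 ± 36.8 CPM (4.43 ± 0.17), and Ctgf, the sarcomere-associated YAP target Ankrd1 and smooth muscle actin Acta2 rose by 3.54 ± 0.13, 2.89 ± 0.23 and 2.15 ± 0.17. NF-kB and inflammatory genes rose in 14 of 19 cases and fell in 3 (adjusted p = 3e-05; adjusted p = 0.105 with an estimated correlation). The prostaglandin synthase Ptgs2 rose by 2.85 ± 0.20, Tnfaip3 by 2.81 ± 0.15 and the apoptosis inhibitor Birc3 by 1.60 ± 0.15. Of 20 immediate early genes, 10 rose and 0 fell (10 and 1 adjusted over the list alone, 10 and 2 without replicate 1 of the knockout rich group; adjusted p = 0.000156; adjusted p = 0.258 with an estimated correlation), Myc by 1.89 ± 0.12. The heme oxygenase Hmox1 and the growth arrest gene Gadd45a rose by 2.90 ± 0.14 and 3.55 ± 0.15. The natriuretic peptide Nppb, at 0.656 ± 0.580 CPM in rich medium, rose by 3.91 ± 0.56, a call lost without either knockout starved library.

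DNA replication genes fell in 28 of 38 cases and rose in 0 (33 and 0 adjusted over the list alone; adjusted p = 5.72e-15; adjusted p = 0.0452 with an estimated correlation, and 0.0899 with it when replicate 1 of the knockout rich group was left out). Cdc6 (-1.71 ± 0.14), the sliding clamp Pcna (-1.41 ± 0.14) and Rrm2 (-1.51 ± 0.11) were among them. Mitosis genes fell in 19 of 32 cases and rose in 0 (20 and 0 adjusted over the list alone; adjusted p = 2.63e-07; adjusted p = 0.203 with an estimated correlation), with the kinesin Kif2c at -1.04 ± 0.11. Cholesterol synthesis genes fell in 15 of 24 cases and fatty acid synthesis genes in 8 of 14, with 0 rises (23 and 12 falls without replicate 1 of the knockout rich group; adjusted p = 3.6e-09 and 0.00312; adjusted p = 0.0723 and 0.11 with an estimated correlation). The isomerase Idi1 changed by -2.08 ± 0.18, the sterol sensor partner Insig1 by -1.98 ± 0.12, Elovl6 by -2.12 ± 0.14 and Scd2 by -1.79 ± 0.15. Hypoxia-inducible targets fell in 10 of 19 cases and rose in 2 (10 and 3 adjusted over the list alone; adjusted p = 0.00393; adjusted p = 0.11 with an estimated correlation). The pyruvate dehydrogenase kinase Pdk1 changed by -1.95 ± 0.13, whereas Ndrg1 rose by 2.12 ± 0.13. Interferon-stimulated genes fell in 8 of 32 cases and rose in 1 (10 and 1 adjusted over the list alone, 12 and 2 without replicate 1 of the knockout rich group; adjusted p = 0.00249; adjusted p = 0.105 with an estimated correlation), with the signal transducer Stat2 at -2.58 ± 0.17. The glucose-responsive arrestin Txnip changed by -4.64 ± 0.17, from 142 ± 2.11 to 5.69 ± 0.840 CPM.

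Autophagy genes moved in both directions in knockout cells, 7 higher and 9 lower of 51 (9 and 10 adjusted over the list alone), with a median of 0.05 that did not differ from other genes (adjusted p = 0.994). This median was -0.01 under scaling by total counts and -0.02 without replicate 1 of the knockout rich group, where 16 genes rose and 20 fell. Without replicate 2 of that group it was 0.21, and 24 genes rose and 18 fell. Sqstm1 rose by 2.11 ± 0.29, Atg12 by 0.78 ± 0.12 and Wdr45 by 0.77 ± 0.14. The mitophagy receptor Bnip3 went from 159 ± 75.7 to 11.6 ± 0.626 CPM (-3.77 ± 0.33), and the lysosomal membrane protein Dram1 and Trp53inp1 changed by -1.75 ± 0.24 and -1.23 ± 0.23. Ulk1 changed by -0.95 ± 0.23. Map1lc3b (-0.39 ± 0.14, adjusted p = 0.0992) and Gabarapl1 (-0.21 ± 0.13, adjusted p = 0.301) did not pass the threshold. Lysosome genes had 6 members higher and 2 lower of 63 (3 and 0 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.183). Without replicate 2 of the knockout rich group the median was 0.42 and passed (adjusted p = 0.0483), and without replicate 1 it was -0.01. The neuraminidase Neu1 rose by 0.68 ± 0.14 and Atp6v1c1 by 0.70 ± 0.14, and both calls were lost without any of 6 libraries in turn.

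The starvation responses of the genotypes shared genes but differed in many of them. Across the 13882 genes the log2 fold changes correlated at r = 0.221 (Spearman's rho 0.273), and at r = 0.319 over genes with a mean of at least 5 CPM. Genes are not independent replicates, and the contrasts share no library. Of 1352 genes called in both genotypes, 1079 changed in the same direction: 498 rose in both (173.8 expected for independent lists) and 581 fell in both (244.5 expected). Without replicate 2 of the knockout rich group r was 0.133. The test of the difference between the responses called 1850 genes, 1030 with a higher and 820 with a lower log2 fold change in the knockout. This count was 7083 and 8007 without replicate 1 and 2 of the knockout rich group, and between 473 and 504 without any other library. Without replicate 1, 3441 were higher and 3642 lower.

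As a list, autophagy genes had a lower response to starvation in the knockout. The difference was called for 14 of 51 members, each lower in the knockout (16 adjusted over the list alone), with a median of -0.42 (adjusted p = 3.11e-05; adjusted p = 0.284 with an estimated correlation; adjusted p = 0.00559 with fry, which tests against no change rather than other genes). It was largest for Bnip3 (-3.78 ± 0.43), which fell in the knockout and did not pass in wild-type cells, and for Trp53inp1 (-3.50 ± 0.33), which rose in wild-type and fell in knockout cells. It was -2.10 ± 0.30 for Atg14, -1.59 ± 0.19 for Nbr1, -1.54 ± 0.19 for Pik3c3, -1.52 ± 0.20 for Wdr45, -1.49 ± 0.22 for Calcoco1 and -1.41 ± 0.18 for Gabarapl1. A lower response need not mean fewer transcripts after starvation. Gabarapl1 and Trp53inp1 were already higher in knockout cells in rich medium, whereas Atg14, Wdr45 and Calcoco1 were lower in starved knockout than in starved wild-type cells. Against wild type the list had a median of 0.116 in rich medium and -0.424 after starvation, and neither passed. For Sqstm1 the responses did not differ beyond the spread (0.56 ± 0.39, adjusted p = 0.378), though they did without replicate 2 of the knockout rich group. Atg12 (-0.84 ± 0.17), Ulk1 (-1.76 ± 0.33) and Map1lc3b (-1.18 ± 0.20) passed, and lost the call without any of 6 libraries in turn. Calcoco1 lost it without 4 libraries and Atg14 without knockout starved replicate 2. Without replicate 1 of the knockout rich group, 31 members were lower and 2 higher, and without replicate 2 the numbers were 23 and 9, with a median of -0.27. Without any other library 6 to 8 members were lower and 0 higher. Lysosome genes had 5 members lower and 3 higher of 63 (7 and 3 adjusted over the list alone) with a median of -0.30 (adjusted p = 0.0207; adjusted p = 0.547 with an estimated correlation; adjusted p = 0.174 with fry). The camera call was lost without replicate 2 of the knockout rich group (median -0.16, adjusted p = 0.279), with 23 lower and 18 higher. Without replicate 1 the numbers were 36 lower and 4 higher, and without any other library at most 1 lower and 0 higher.

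**Figure D4:**
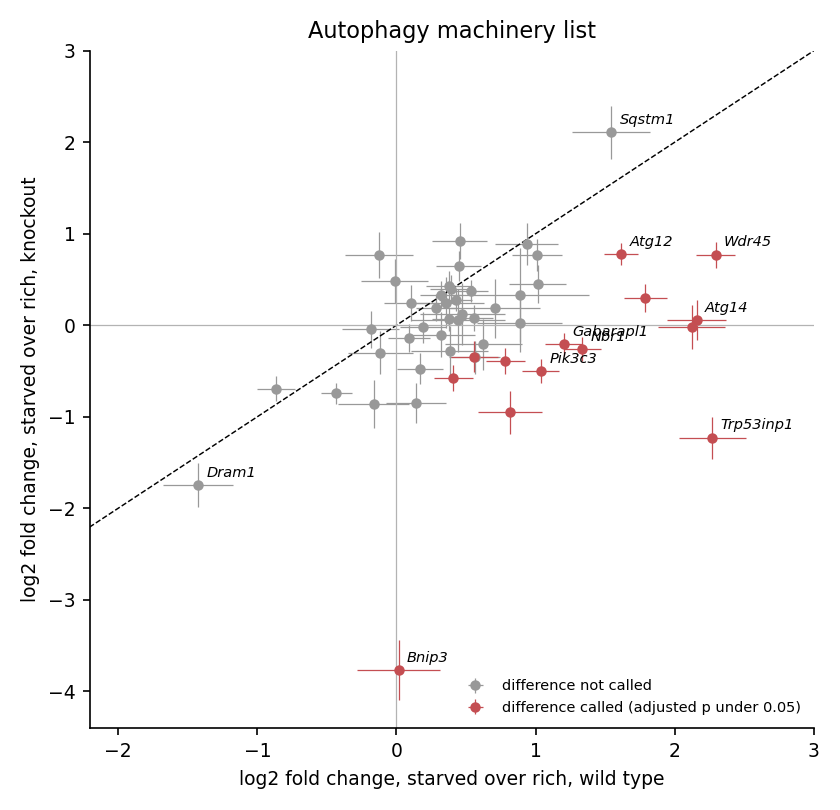
Log2 fold change after starvation of the 51 autophagy genes in wild-type (horizontal) and knockout cells (vertical), with SE as error bars and equality as the dashed line. The 14 genes called for the difference between the responses, in red, lie below the line, and Sqstm1 rose in both genotypes.

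Larger differences were found for groups that moved in opposite directions. Contractile genes and YAP targets differed in 15 of 18 cases and NF-kB and inflammatory genes in 13 of 19, each with the higher response in the knockout (17 and 13 adjusted over the list alone; adjusted p = 2.93e-12 and 1.41e-09; adjusted p = 0.097 and 0.0717 with an estimated correlation). The difference was 6.71 ± 0.23 for Cyr61, 6.43 ± 0.18 for Ctgf, 6.42 ± 0.19 for Ccl2 and 6.71 ± 0.22 for Tnfaip3. Of 38 DNA replication genes, 23 responded lower in the knockout and 0 higher (26 and 0 adjusted over the list alone, 35 and 1 without replicate 1 of the knockout rich group; adjusted p = 1.67e-13; adjusted p = 0.0711 with an estimated correlation), with Cdc6 at -2.67 ± 0.19. Mitosis genes, which fell in both genotypes, fell less in the knockout in 12 of 32 cases (15, and 3 with a larger fall, adjusted over the list alone; adjusted p = 0.00819; adjusted p = 0.424 with an estimated correlation). The rise of ER chaperones was smaller in the knockout for 11 of 25 genes and larger for 1 (15 and 2 adjusted over the list alone; adjusted p = 0.000123; adjusted p = 0.0893 with an estimated correlation), and that of the ATF4 list was smaller for 9 of 33 and larger for 1 (13 and 2 adjusted over the list alone; adjusted p = 0.00564; adjusted p = 0.547 with an estimated correlation). Without replicate 1 of the knockout rich group, the response was lower for 21 ER chaperones and 24 members of the ATF4 list, higher for 2 and 3, and for mitosis genes higher for 22 and lower for 5. The difference was -1.51 ± 0.21 for Ddit3 and -1.25 ± 0.16 for Sel1l. Of the 38 lists, 15 passed with the preset and 0 with an estimated correlation.

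In rich medium knockout cells had far fewer transcripts of interferon-stimulated genes than wild-type cells. Among inflammatory and extracellular matrix genes some were far higher and others lower, and neither list passed as a whole. Transcripts of some positional and imprinted genes present in one genotype were nearly absent from the other. In all 6114 genes differed, 3248 higher and 2866 lower in the knockout, a balance that reversed under scaling by total counts (2893 and 3168) and without replicate 2 of the knockout rich group (4903 and 5448). The count was 9313 and 10351 without replicate 1 and 2 of the knockout rich group, 3553 and 3431 without replicate 1 and 2 of the wild-type rich group, 3184 in a fit of the 4 libraries compared and 3749 with library quality weights.

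Of 32 interferon-stimulated genes, 28 were lower and 2 higher (adjusted p = 8.55e-11; adjusted p = 0.0494 with an estimated correlation, and 0.161 with it when replicate 1 of the knockout rich group was left out). The transcription factor Irf7 stood at 50.3 ± 2.61 CPM in wild-type and 0.309 ± 0.0883 CPM in knockout cells (-7.21 ± 0.28). Irf9, Rtp4 and Cxcl10 were lower as well (-4.47 ± 0.18, -7.34 ± 0.29 and -7.20 ± 0.30). Of 19 NF-kB and inflammatory genes, 10 were higher and 4 lower, with a median of 0.80, which did not pass as a list (adjusted p = 0.0734). Without replicate 1 of the knockout rich group the median was 0.98, and the list passed with the preset but not with an estimated correlation. The siderophore-binding protein Lcn2 went from 0.765 ± 0.228 to 291 ± 77.3 CPM (8.54 ± 0.31), the chemokine gene Ccl7 was higher by 4.55 ± 0.18, and the acute phase gene Saa3 was 990-fold higher (95% counting interval 338 to 4800). Leukocyte markers were higher in 5 of 6 cases and lower in 0 (6 adjusted over the list alone; adjusted p = 0.00483; adjusted p = 0.379 with an estimated correlation), with the tetraspanin Cd53 at 0 counts in wild-type and 21.9 ± 3.21 CPM in knockout cells, at least 326-fold higher. Of the 6, 4 had 0 to 3 counts in the wild-type group. These entered the test only through the knockout libraries, which fixed their direction. Of 5 endothelial markers, 3 were higher and 2 lower (adjusted p = 0.776). The endothelial cadherin Cdh5, at 140.1 ± 19.6 CPM in the knockout, was 3440-fold higher (951 to 28400).

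Of 34 extracellular matrix genes, 14 were higher and 15 lower (adjusted p = 0.921). The proteoglycan decorin, Dcn, stood at 0.453 ± 0.115 CPM in wild-type and 1663 ± 412 CPM in knockout cells (11.80 ± 0.32). The collagen gene Col6a3 and the crosslinking enzyme Lox were higher by 4.62 ± 0.19 and 2.46 ± 0.13, and the basement membrane collagen gene Col4a2 differed by -5.37 ± 0.18. Contractile genes and YAP targets were lower in 11 of 18 cases and higher in 3 (adjusted p = 0.0174; adjusted p = 0.65 with an estimated correlation), with Ctgf at -3.68 ± 0.13 and Cyr61 at -2.76 ± 0.16. Hypoxia-inducible targets were higher in 12 of 19 cases and lower in 4 (14 and 4 adjusted over the list alone; adjusted p = 0.0283; adjusted p = 0.41 with an estimated correlation), including the vascular growth factor Vegfa (2.76 ± 0.14) and Ndrg1 (2.25 ± 0.13). Of 51 autophagy genes, 13 were higher and 4 lower (21 and 10 without replicate 1 of the knockout rich group; adjusted p = 0.616), with Gabarapl1, the receptor Optn and Trp53inp1 higher by 2.04 ± 0.14, 2.42 ± 0.19 and 2.90 ± 0.25. Of 63 lysosome genes, 9 were higher and 16 lower (9 and 15 adjusted over the list alone; 18 and 25 without replicate 1 of the knockout rich group; adjusted p = 0.5), with the protease Ctsl at 2.97 ± 0.22 and the ganglioside activator Gm2a at -3.80 ± 0.24. Of 14 arginine methyltransferase and coactivator genes, 5 were higher and 4 lower (5 and 5 adjusted over the list alone; adjusted p = 0.921), with Prmt2 at -1.90 ± 0.15.

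Hox genes, which mark position along the body axis, were higher in 11 of 19 cases and lower in 5 (adjusted p = 0.152). Hoxa11, which patterns the limb, was at least 415-fold lower in the knockout and Hoxb3 was 411-fold higher (113 to 3400). The hindlimb factor Pitx1 was at least 510-fold lower, while the transcription factor Foxf1 was higher by 4.45 ± 0.20. Of 17 imprinted genes, 6 were higher and 8 lower (adjusted p = 0.921). Peg10, a paternally expressed gene, was at least 1340-fold lower, Grb10 differed by -7.65 ± 0.29, and the maternally expressed RNAs Meg3 and Rian were higher by 7.43 ± 0.31 and 8.21 ± 0.28. The death receptors Fas and Eda2r and the cystine transporter Slc7a11 were higher by 3.82 ± 0.16, 4.75 ± 0.27 and 3.76 ± 0.17.

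After starvation knockout cells had more transcripts of inflammatory, immediate early and contractile genes than wild-type cells and fewer of DNA replication, ER chaperone and interferon-stimulated genes. In all 7586 genes differed, 3864 higher and 3722 lower, and 11271 without replicate 1 of the knockout rich group (5558 and 5713). Scaling by total counts moved the median of all genes to -0.14 in this contrast, from -0.02, and the counts to 3463 higher and 4205 lower. Genotype differences in the media correlated across genes at r = 0.879, with no library shared, and of 4530 genes called in both, 4314 differed in the same direction.

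NF-kB and inflammatory genes were higher in 17 of 19 cases and lower in 1 (adjusted p = 7.81e-08; adjusted p = 0.127 with an estimated correlation). Ccl2 stood at 1.73 ± 0.195 CPM in wild-type and 415 ± 16.6 CPM in knockout cells (7.90 ± 0.17), and Cxcl1 was higher by 7.47 ± 0.16. Beside them, all 6 tested leukocyte markers were higher (adjusted p = 0.00172; adjusted p = 0.165 with an estimated correlation), Cd53 at least 183-fold. Of these, 4 again had 0 to 3 counts in the wild-type group, so their direction was fixed by the filter. Immediate early genes were higher in 16 of 20 cases and lower in 0 (16 and 1 adjusted over the list alone; adjusted p = 6.62e-06; adjusted p = 0.343 with an estimated correlation), Fosl1 by 4.87 ± 0.17 and Egr1 by 3.79 ± 0.13. Contractile genes and YAP targets were higher in 14 of 18 cases and lower in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.00109; adjusted p = 0.527 with an estimated correlation), Cyr61 by 3.95 ± 0.17 and Ctgf by 2.75 ± 0.12, the reverse of their difference in rich medium. The matricellular gene Thbs1 was higher by 5.17 ± 0.15.

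DNA replication genes were lower in 29 of 38 cases and higher in 1 (32 and 1 adjusted over the list alone; adjusted p = 7.81e-08; adjusted p = 0.127 with an estimated correlation), with Cdc6 and the replication factor Mcm10 at -2.64 ± 0.14 and -2.01 ± 0.14. ER chaperone genes were lower in 15 of 25 cases and higher in 1 (16 and 1 adjusted over the list alone; adjusted p = 0.00224; adjusted p = 0.165 with an estimated correlation), with Manf at -1.43 ± 0.13 and Herpud1 at -1.36 ± 0.16. Interferon-stimulated genes were lower in 26 of 32 cases and higher in 2 (adjusted p = 8.87e-07; adjusted p = 0.127 with an estimated correlation), with Irf7 at -6.13 ± 0.24. Of 51 autophagy genes, 21 were lower and 9 higher (22 and 9 adjusted over the list alone), with a median of -0.42 that did not pass against other genes (adjusted p = 0.11). Calcoco1 stood at 124 ± 3.58 CPM in wild-type and 22.9 ± 1.71 CPM in knockout cells (-2.43 ± 0.16), Atg14 and Wdr45 differed by -2.63 ± 0.21 and -1.78 ± 0.14, and Optn was higher by 2.19 ± 0.18. Lysosome genes were lower in 26 of 63 cases and higher in 8 (40 and 10 without replicate 1 of the knockout rich group), with a median of -0.45 (adjusted p = 0.0224; adjusted p = 0.771 with an estimated correlation), with Gm2a at -3.49 ± 0.23 and Neu1 at -1.92 ± 0.14. Xist, Peg10 and Grb10 kept the direction they had in rich medium (-8.32 ± 0.29 for Grb10, and at least 1690-fold lower for Peg10).

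**Figure D5:**
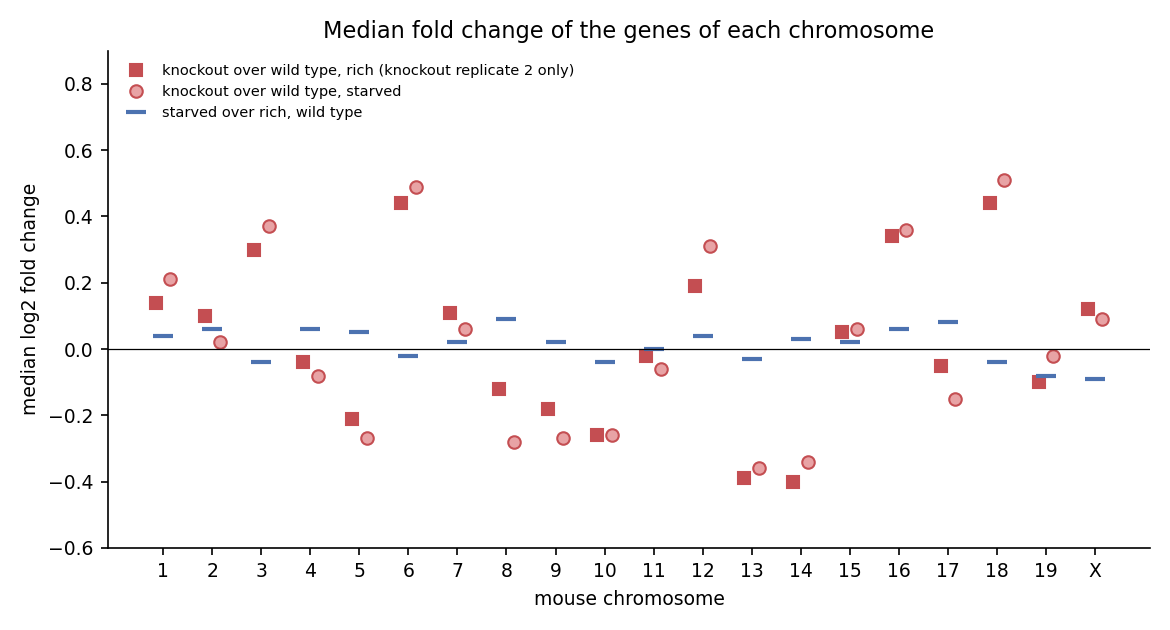
Median log2 fold change of the genes with at least 10 CPM on each mouse chromosome, for knockout against wild type in rich medium (squares, knockout replicate 2 only) and after starvation (circles) and for starvation in wild-type cells (bars). Knockout against wild type, medians run from -0.36 on chromosome 13 to 0.51 on chromosome 18 after starvation, with like values in rich medium, whereas the starvation medians lie between -0.09 and 0.09.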

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

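Most values here come from the test of the difference between the starvation responses of the genotypes, written as the knockout response minus the wild-type response on the log2 scale. Chosen after the results were seen were the tests of wild-type RNA, of a stable population difference and of CARM1 loss against other differences, the repeat of the matched-list test without a library, and the use of camera p-values for the lists.

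The responses differed for 1850 genes and for 15 gene lists. Lists with a lower response in the knockout were DNA replication (adjusted p = 1.67e-13), autophagy (3.11e-05), ER chaperones (0.000123), FOXO targets (0.0023, with 8 of 17 members lower and 2 higher), ribosomal proteins (0.0023, with 3 of 77 lower, 0 adjusted over the list alone and 74 without replicate 1 of the knockout rich group), the ATF4 list (0.00564), hypoxia-inducible targets (0.0107, with 9 of 19 lower and 1 higher) and the lysosome (0.0207). Lists with a higher response were contractile genes and YAP targets (2.93e-12), NF-kB and inflammatory genes (1.41e-09), immediate early genes (1.1e-07, with 11 of 20 higher, and 13 higher and 1 lower adjusted over the list alone), interferon-stimulated genes (8.58e-07, with 5 of 32 higher and 1 lower, and 6 and 1 adjusted over the list alone), replication-dependent histones (1.48e-06, with 6 of 24 higher, 14 adjusted over the list alone), mitosis (0.00819) and the extracellular matrix (0.0118, with 8 of 34 higher, and 11 higher and 1 lower adjusted over the list alone). With an estimated correlation none of the 38 lists passed, and the FOXO, hypoxia, immediate early and histone lists had an adjusted p of 0.158, 0.171, 0.171 and 0.332. Without replicate 1 of the knockout rich group 14 interferon-stimulated, 14 histone and 15 matrix genes were higher, and 2, 0 and 4 lower. With all libraries the estimated-correlation adjusted p was 0.609 for ribosomal proteins, 0.0711 for interferon-stimulated genes and 0.439 for the extracellular matrix. Interferon-stimulated genes still fell in the knockout (median -0.605, against -1.986 in wild-type cells). Their median in rich medium was already -4.72 against wild type, and 6 of 32 had 0 to 3 counts in a knockout group. Their low level limits how far they could fall, which may give part of this difference. Of the 24 histone genes, 9 had 0 to 3 counts in a wild-type group, so their differences are less certain.

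Named autophagy genes with a differing response were Trp53inp1 (-3.50), Bnip3 (-3.78), Nbr1 (-1.59), Pik3c3 (-1.54), Wdr45 (-1.52), Atg14 (-2.10), Calcoco1 (-1.49), Gabarapl1 (-1.41), Atg12 (-0.84), Ulk1 (-1.76) and Map1lc3b (-1.18). Among lysosome genes the acetyltransferase Hgsnat (0.92) and Fuca1 (1.00) had a higher response and the protective protein Ctsa (-0.89) a lower one, and these 3 calls were lost without any library outside the knockout rich pair. Contractile genes and YAP targets included Ctgf (6.43), Cyr61 (6.71) and Ankrd1 (4.61), and inflammatory genes Ccl2 (6.42), Cxcl1 (5.99), Tnfaip3 (6.71) and Csf1 (4.08). The immediate early genes Egr1 and Fosl1 differed by 4.24 and 3.52. DNA replication genes with a lower response were Cdc6 (-2.67) and the ligase Lig1 (-1.75), and mitosis genes with a higher one Ube2c (2.11), Plk1 (1.79) and Aurka (1.70). Stress genes with a lower response were Sel1l (-1.25), Manf (-1.17), the mannosidase-like Edem1 (-1.57), Ddit3 (-1.51) and Aldh1l2 (-1.53), of which Manf lost the call without any of 5 libraries. The remaining named genes were Txnip (-2.87), the zinc finger factor Klf10 (2.44), the linker histone Hist1h1c (6.28), Thbs1 (4.22) and the kinase Plk2 (3.93).

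The lower starvation response of the autophagy list in the knockout was weighed against 3 explanations. Replicate 1 of the knockout rich group alone does not account for the lower response, since the median difference was -0.432 without it. The list then passed camera with the preset but not with an estimated correlation. Whether the list merely shares a response that is smaller for all genes cannot be told apart from a list-specific difference: its median knockout response lay at percentile 5.65 of 10000 random lists matched on wild-type response and expression, inside the central range, but at percentile 1.05 without that library, outside it. With all libraries the matched lists had a median knockout response of 0.203, against 0.052 for the autophagy list. Without replicate 2 the median difference was -0.275, and the matched-list test was not run. Which replicate is atypical is not known. Loss of CARM1 and other differences between the cell populations cannot be told apart either, because 44% of the genes tested differed between the genotypes in rich medium and the labels do not say how many cell populations represent each genotype.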

How the results depend on the processing

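Alternatives were planned except library quality weights and the transcript choices, which were chosen after seeing the data. Of 3920 values for the 198 named gene results, 3777 kept their direction and side of the threshold, 138 lost the call, 5 gained it and 0 reversed; 139 results held under each alternative run. Under RLE factors, limma-voom, a minimum change of 1.5-fold and both transcript choices all named gene results held, and the fit of only the 4 libraries compared lost 44 calls, all in knockout starvation. Counts of genes depended on which library was left out. All groups share the wide spread of the knockout rich pair, for which the quality weights were 0.106 and 0.167, against 1.645 to 2.201 for the others.

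In fits of only the 4 libraries compared, edgeR called 9382 genes for wild-type starvation, 0 for knockout starvation (2831 at an unadjusted p under 0.05) and 3184 for the knockout in rich medium, where the spread is estimated from fewer samples. Library quality weights gave 9393, 1319 and 3749, and DESeq2 gave 2880 for the difference between responses; the cause was not tested. Leaving out each library in turn, which assumes that the lone sample left varies like the other groups, gave 1626 to 9511 genes for wild-type starvation, 278 to 8419 for knockout starvation, 3431 to 10351 for the knockout in rich medium, 5212 to 11273 after starvation and 473 to 8007 for the difference. The highest counts came without a knockout rich library, when the lone library left adds nothing to the shared estimate of the spread. The lowest came without another library, when the knockout rich pair makes up a larger share of that estimate. Whether this alone sets the counts was not tested. The correlation of the responses ranged from 0.133 (without knockout rich replicate 2) to 0.223, and was 0.297 with the stricter filter, which tests fewer genes.

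With an estimated correlation the medians of the autophagy list in wild-type starvation and in the difference (0.447 and -0.422) no longer passed (adjusted p = 0.199 and 0.284), nor did those of the lysosome list (0.399 and -0.305; adjusted p = 0.38 and 0.547). Over the libraries left out, the autophagy medians ran from 0.387 to 0.523 in wild-type starvation, -0.016 to 0.214 in knockout starvation and -0.551 to -0.275 in the difference, and the first and last passed throughout. Those of the lysosome list ran from 0.317 to 0.419, -0.007 to 0.424 and -0.404 to -0.161; without knockout rich replicate 2 the list passed in knockout starvation (0.424, adjusted p = 0.0483) and failed in the difference (-0.161, adjusted p = 0.279), and the cause was not tested.

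Replicate numbers recur in all groups, and the deviations of same-numbered libraries were nearly uncorrelated across genes (correlations of -0.026 to 0.063). Replicates differed little in most groups, so a shared culture or preparation is not excluded, and the labels do not say. With a replicate block the counts were 4123, 2111, 5802, 7361 and 1490 in the order of the contrasts, and Fuca1 lost its call in the difference. The library with the fewest counts (8447016) allows up to 0.355 CPM where a gene has 0 counts, against 0.107 to 0.146 CPM in the others.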

Other observations

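The tests of wild-type RNA and of a stable population difference were chosen after the results were seen. Several groups outside the comparisons above also changed. FOXO targets rose in 7 of 17 cases and fell in 1 in starved wild-type cells (adjusted p = 0.043; adjusted p = 0.24 with an estimated correlation), a call lost without replicate 1 of the knockout rich group (adjusted p = 0.245), and in knockout cells 4 rose and 8 fell (5 and 10 adjusted over the list alone; adjusted p = 0.0985). Of 21 p53 targets, 6 rose and 2 fell in wild-type starvation (14 and 3 without replicate 1 of the knockout rich group; adjusted p = 0.0289; adjusted p = 0.199 with an estimated correlation). Extracellular matrix genes fell in 18 of 34 cases and rose in 2 (21 and 2 adjusted over the list alone; adjusted p = 3.8e-05; adjusted p = 0.268 with an estimated correlation), and replication-dependent histones fell in 12 of 24 cases and rose in 0 (14 and 0 adjusted over the list alone; adjusted p = 1.55e-05; adjusted p = 0.328 with an estimated correlation). Of the 24 histone genes, 9 had 0 to 3 counts in a wild-type group. The histone median was -2.886 as fitted and -2.418 with these genes set to their bounds. Transcription factors that mark positions in mesenchyme fell in 12 of 28 cases and rose in 1 (13 and 1 adjusted over the list alone, 20 and 4 without replicate 1 of the knockout rich group; adjusted p = 0.00169; adjusted p = 0.133 with an estimated correlation). In knockout starvation Hox genes fell in 7 of 19 cases and rose in 1 (8 and 1 adjusted over the list alone, 11 and 1 without replicate 1 of the knockout rich group; adjusted p = 0.00176; adjusted p = 0.146 with an estimated correlation), and 5 of 14 arginine methyltransferase and coactivator genes rose and 0 fell (6 and 0 adjusted over the list alone, 9 and 2 without replicate 1 of the knockout rich group; adjusted p = 0.0218; adjusted p = 0.275 with an estimated correlation). Respiratory chain genes, tricarboxylic acid cycle genes, NRF2 targets and clock genes did not pass in either starvation contrast (adjusted p = 0.284, 0.79, 0.114 and 0.965 in wild-type and 0.503, 0.893, 0.754 and 0.994 in knockout cells).

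Some genes had counts in libraries of a single genotype. Ifi202b, an interferon-inducible gene that C57BL/6 mice are known not to express, had 0 counts in the 4 wild-type libraries and 2074 to 3615 in the knockout libraries, although the labels give C57BL/6 for both. Grb10 had 9266 to 16076 counts in wild-type and 18 to 57 in knockout libraries, Sgce 775 to 961 and 0, and Rian 6 to 14 and 1447 to 3223. Hmgcs1, a gene of cholesterol synthesis, had 0 counts in all 8 libraries and was singled out after this was seen. A segment of another strain retained around Carm1 was tested as a source of the many genes that differ in both media. Of the 50 tested genes nearest to Carm1, 26% differed in both media in the same direction, below the 95th percentile of windows of that size (median 30%). Genes near Carm1 thus differed no more often than those of other windows. With differing genes this frequent elsewhere, the test cannot tell whether such a segment adds to them. A strain difference across the genome was not tested.

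Replicate 1 of the knockout rich group stood apart from replicate 2, with a standard deviation of the log2 ratio of 0.748. Low depth argues little, since pairs of the other groups reached at most 0.151 with a library thinned to its depth. A trend on gene span, with which the ratio correlated at 0.317, left a standard deviation of 0.706 when removed. Wild-type RNA is excluded as the main cause, as 6 transcripts specific to wild-type cells stood at 0.028% of their wild-type level (upper bound 0.081%). A difference in culture state or in base composition of the reads could not be tested, and no biological explanation was tested because the design gives none within a group.

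Medians of whole chromosomes differed between the genotypes, and also between the knockout rich replicates (standard deviation 0.229, with -0.44 on chromosome 7 and 0.32 on X). After starvation the median log2 fold change of knockout against wild type was 0.51 on chromosome 18 (most abundant gene Hspa9), where 75.8% of genes were higher, 0.49 on chromosome 6 (Gapdh), -0.36 on chromosome 13 (Ctsl) and -0.34 on chromosome 14 (Tpt1). The standard deviation of the 20 medians was 0.279, and at most 0.0811 in shuffles of single genes over chromosomes (permutation p = 0.001, the smallest that 1000 shuffles give). This argues against chance placement of independent genes. The shuffles break up neighbouring genes that vary together, so chance placement of such groups is not excluded. Of the standard deviation, 98.4% remained after regression on the difference between the knockout rich replicates, gene span and expression. The medians recurred across chromosomes in knockout rich replicate 2 against wild-type rich (r = 0.968) and less closely in replicate 1 (r = 0.843, added after the first value was seen), while the starvation responses had standard deviations of 0.0516 in wild-type and 0.087 in knockout cells. A stable difference between the cell populations, such as a changed number of chromosomes in part of the cells, may underlie part of the shifts as a hypothesis. Copy number was not measured, and a library batch that coincides with genotype stays open. The 98.4% left after regression argues against a library effect with the pattern of the replicate difference. The medians of that difference correlated with the starved medians at only 0.302. A library effect of another pattern stays open.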
